A study of Homo sapiens with 16 samples.

How the data were processed

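RNA was sequenced from 16 samples of hypothalamus-pituitary organoids grown from the human induced pluripotent stem cell line 201B7. The line carries GFP behind PITX1 and mCherry behind NKX2-1. Per the labels, organoids were sorted by a machine-learning prediction into a fail and a success group and collected at day 9 or day 15, which makes 4 groups of 4 libraries. The labels give a replicate number from 1 to 4 in each group, and library numbers 58 to 61 at day 9 and 57 to 60 at day 15. The library names of both days carry different prefixes, so day and library series cannot be told apart. Nothing in the labels says that the 4 samples of a group came from separate cultures. P-values therefore measure only the spread between these samples, which may be technical.

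The deposited table holds whole-number counts of reads per gene, not normalized, for 38608 genes in 16 columns, each of which matched the labels of 1 sample. Per the labels' protocols, RNA was purified on columns and libraries were made with a stranded poly-A kit. Per the submitters' processing notes, the tools were bcl2fastq 2.20, cutadapt 4.6, STAR 2.7.11a and HTSeq 2.0.5 with the genome build GRCh38. The annotation release, the strand setting of the counting and any read filters are not given in the sources used here. Reads of overlapping and antisense genes can therefore not be told apart with certainty. Genes with near-identical copies, such as ribosomal protein genes, POU5F1, NANOG and the growth hormone genes, are uncertain where reads map to more than 1 place. The table has entries for the reporters EGFP and mCherry. Of its counts 0% lay outside gene entries, which does not give the share of reads left unassigned to a gene.

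Totals ran from 16.3 to 22.3 M counts per library. Genes with enough counts in a group by edgeR's filterByExpr were kept, which left 17164 genes. Counts were scaled by trimmed mean of M values and compared with edgeR 4.0.16 (quasi-likelihood F test, two-sided) in R 4.3.3. One fit over the 16 libraries with the 4 groups as its terms gave all 5 comparisons: success against fail at day 9 and at day 15, day 15 against day 9 in success and in fail, and the interaction of outcome and day. The fit held no replicate block, since no method of the study that uses one was at hand. Its standard errors, intervals and p-values therefore ignore any pairing of samples by number, and fits with the block were run as alternatives. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Standard errors were taken as the absolute log2 fold change over the root of F. The common biological coefficient of variation was 0.203. CPM values are counts scaled per M of the normalized total, and log2 CPM used a prior count of 2.

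Gene lists for tissue identity, signalling, metabolism, stress, cell cycle and organelles were fixed before the data were examined, 34 in all. A list needed 5 measured members, which left 33, since the pituitary hormone list had too few. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list moved more than the other genes. Camera with the correlation estimated per list and the rotation test fry, which asks whether the genes of a list move on balance 1 way, were run beside it. Medians of lists are medians of edgeR log2 fold changes, except among the alternatives, where they come from the voom fit.

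Named genes were chosen by a rule written before the data were examined. It takes PITX1, NKX2-1, HESX1, LHX3, LHX4, SIX6, RAX and POU5F1 in every comparison. Some genes that the rule covers are not reported here, and no others were put in their place. Among called genes with an approved symbol, at least 5 CPM in the higher group and no overlap between both groups' libraries, it takes the 6 largest rises and the 6 largest falls. It adds the 2 members with the smallest p of each list that camera called, and, where fewer than 6 genes passed, the 6 with the smallest p. EGFP and mCherry were added after the table was seen. Other genes named are said to have been chosen after their values were seen.

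Whether replicate numbers pair samples was checked from the correlation of the deviations from the group means between fail and success libraries of a day. At day 15 the 4 same-number pairs had correlations of 0.256 to 0.481 over the 500 genes whose deviations varied most. Every fail library correlated best with the success library of its own number. In the other direction, success replicate 3 correlated better with fail replicate 4 (0.291) than with fail replicate 3 (0.256). The numbers were taken to pair the samples. The pairing comes from this check, as the labels do not say what a number marks. It stays uncertain, as 3 of 24 ways to pair the day 15 libraries called at least the 15 genes of the real one. No pair of libraries within a group agreed within sampling noise, since the chi-square per degree of freedom was 7.12 or more.

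Transcript length was taken from the longest coding transcript of GENCODE release 29 on GRCh38, which gave a length for 96.9% of the genes tested. Positions of genes come from the same release. The length slope of a library is the slope of its deviation from the mean of the 16 libraries on log2 transcript length, with GC content in the same model, over genes with a mean log2 CPM above 0. Distances between libraries used the 500 most variable genes in log2 CPM. Comparisons of single values used exact permutation tests, two-sided.

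The tests were run on simulated counts with 200 changed genes drawn from the real means and library sizes. In these, 4.95% and 4.74% of the unchanged genes had an unadjusted p under 0.05 for success against fail at day 9 and day 15, against 0.425% and 1.31% of the real genes, so the simulation does not give the real power. For success against fail, edgeR called 67.7% of the 2-fold changes at day 9 and 72.3% at day 15, and 20.0% and 33.8% of the 1.5-fold changes. For day 15 against day 9 it called 56.7% of the 2-fold changes in success and 61.2% in fail, and 37.3% for the interaction. Of the genes called, 2.59 to 5.97% had not been changed. A list shifted by 0.5 log2 was called in 5 of 5 simulated comparisons and no other list (0) was. Genes were drawn independently in these counts, so the simulation does not test how camera acts on correlated genes.

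Alternatives fixed before the data were examined were DESeq2 1.42.0, relative log expression factors, library totals alone, no low count filter, at least 1 CPM in 4 libraries, limma voom with and without sample weights, a robust fit, a log2 fold change of at least 1, the replicate number or library number as a block, a fit on only the groups compared, and leaving out each library. Chosen after seeing the data were leaving out both day 9 libraries that stood apart and the length trend of each library as a covariate.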

Results

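Gene counts came from bulk RNA sequencing of 16 libraries of organoids that model the hypothalamus and the pituitary together. They were grown from 201B7, an established human induced pluripotent stem cell line, here with GFP behind PITX1 and mCherry behind NKX2-1. PITX1 is a transcription factor of oral ectoderm and pituitary, and NKX2-1 is one of the ventral forebrain and hypothalamus. A machine-learning model had predicted which organoids would fail and which would succeed. Each group (fail or success, at day 9 or day 15) had 4 libraries. Outcome names here refer to that prediction, not to what an organoid later formed. Mean totals were 19.3 ± 0.510 M counts in day 9 fail, 19.7 ± 2.12 in day 9 success, 17.5 ± 0.966 in day 15 fail and 19.8 ± 0.789 in day 15 success (SD, n = 4 each).

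Libraries separated by day along the first principal component, which held 59.9% of the variance of the 500 most variable genes. Fail and success libraries did not separate along it. Day 9 fail replicate 2 and day 9 success replicate 4 stood apart, at -9.71 and 2.15 on that component, where the other 6 day 9 libraries lay between -33.6 and -21.1 and the day 15 libraries between 9.96 and 33.7. In both, long transcripts were lower, with length slopes of -0.0966 and -0.192 log2 per doubling of length against 0.118 to 0.164 in the other 6. Day 15 libraries had slopes of -0.129 to 0.0357. The 28 ribosomal protein genes of the list took 5.55% and 6.48% of their counts, against 4.07 to 4.35% in the other 6 and 5.08 to 6.40% at day 15. PITX1 in both, at 1.04 and 1.47 log2 CPM, was in the day 9 range and below the lowest day 15 library at 2.77. Both libraries were kept in every comparison, and the counts of genes and lists without them are given with each.

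**Figure D1:**
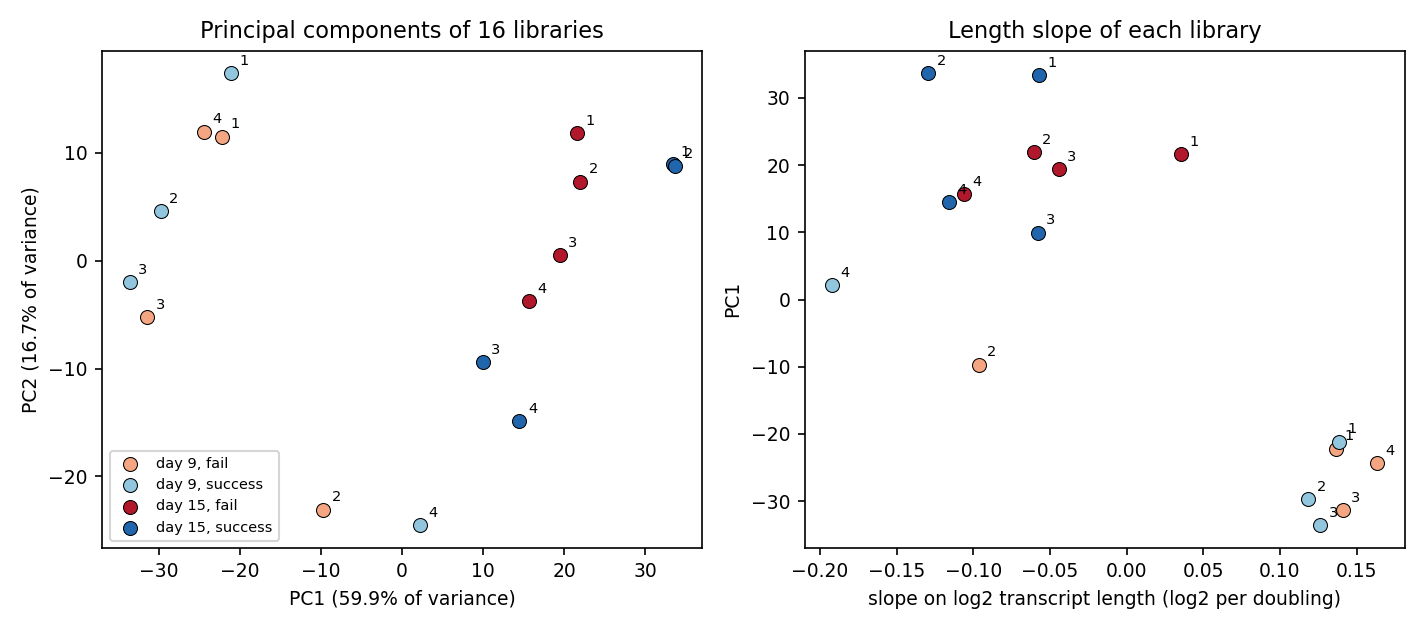
Left, the first principal component (59.9% of the variance) against the second (16.7%) for 16 libraries, coloured by group and numbered by replicate. Right, the slope of each library on log2 transcript length (log2 per doubling) against the first component. Day 9 fail replicate 2 and day 9 success replicate 4 lie apart from the other 6 day 9 libraries on both axes, with slopes of -0.0966 and -0.192.

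The change from day 9 to day 15 in the success group asks how these organoids developed. PITX1, on chromosome 5 from 135027735 to 135034813 (GRCh38, minus strand), rose by 2.36 log2 (SE 0.30, adjusted p = 0.000327), from 2.21 ± 0.470 to 11.3 ± 0.518 CPM (SD, n = 4). The transcript of its reporter, EGFP, rose by 2.65 (SE 0.37, adjusted p = 0.000701), and that of SIX6, a transcription factor of the eye field and the hypothalamic-pituitary region, by 0.80 (SE 0.27, adjusted p = 0.0430). Of pluripotency genes, LIN28A, an RNA-binding protein of stem cells, fell by 1.3 (SE 0.29) and the transcription factor SALL4 by 0.55 (SE 0.13). In the 2 day 9 libraries that stood apart, LIN28A was at -0.61 and -1.18 against the other 6. SALL4 was at 0.11 and -0.27 and SIX6 at 0.57 and 0.33 in them. NKX2-1 (0.41, SE 0.32), mCherry (0.44, SE 0.33), RAX (0.41), LHX4 (-0.44), HESX1 (-0.40) and POU5F1 (-1.02, SE 0.65) did not pass, with adjusted p from 0.262 to 0.472.

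Across all genes in the success group, 1769 rose and 1908 fell, of which 505 and 805 changed at least 2-fold. Among called genes with at least 5 CPM in 1 group and no overlap between the groups' libraries, large rises were S100A9, a calcium-binding protein of myeloid cells and stressed epithelia, at 4.89 (SE 0.67), and the muscle genes HSPB7, a small heat shock protein, at 4.32 (SE 0.48) and MYL7, the atrial myosin light chain, at 3.87 (SE 0.69). DCT, an enzyme of melanin synthesis, reached 3.76 (SE 0.55), PDK4, an inhibitor of pyruvate dehydrogenase, 3.58 (SE 0.41), and COL3A1, a fibrillar collagen, 3.54 (SE 0.56), from 30.9 ± 13.0 to 360.2 ± 214 CPM (SD, n = 4). In the same set large falls were SEC31B at -2.38 (SE 0.60), TNFRSF8 at -2.14, ADGRG2 at -2.11, CCDC92B at -2.11, the tryptophan-degrading enzyme IDO1 at -2.04 and RIPPLY3 at -1.85 (SE 0.33). SEC31B was also lower in both day 9 libraries that stood apart, by -2.91 and -2.10 against the other 6, CCDC92B by -0.46 and -1.48 and RIPPLY3 by -0.57 and -0.60. TNFRSF8, ADGRG2 and IDO1 were higher in fail replicate 2 and lower in success replicate 4. Of the rises, MYL7 was higher in both, by 1.72 and 1.94, and COL3A1 by 0.33 and 0.52. S100A9 (1.76 and -1.06), DCT (1.25 and -1.06) and PDK4 (-0.53 and 0.96) were split, and HSPB7 was lower (-0.81 and -0.06).

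Camera called 15 of the 33 gene lists between the days in the success group, 11 of them up and 4 down. BMP response genes rose: 12 of 17 passed upward (13 adjusted over the list alone), the median was 0.57, and examples are ID2 at 0.82 (SE 0.12) and MSX1 at 0.95 (SE 0.21). This list was also called with an estimated correlation (adjusted p = 0.0203). Hypoxia and glycolysis genes rose in 16 of 23 members (21 over the list alone, median 0.58). Among them were the collagen hydroxylase P4HA2 at 0.98 and the glycolytic enzyme ALDOA at 1.27. The retinoic acid list rose in 3 of 15 (6 over the list alone, median 0.44), with the retinaldehyde dehydrogenase ALDH1A3 at 2.15 (SE 0.28) and the receptor RARB at 1.29. Their calls were lost with an estimated correlation (adjusted p = 0.0643 and 0.106). Mesenchyme and matrix genes rose in 8 of 19 (8 over the list alone, median 0.78, ACTA2 at 1.48). Amnion and trophoblast genes rose in 4 of 13 (5, median 0.66, ISL1 at 1.58 and BAMBI at 1.04) and eye field genes in 5 of 9 (5, median 0.50, MITF at 1.00). Surface ectoderm genes rose in 4 of 16 (4, median 0.35, KRT17 at 1.67). The adjusted p with an estimated correlation was 0.407 for mesenchyme and for amnion and 0.501 for eye field and for surface ectoderm. Of stress lists, p53 targets rose in 9 of 21 (10, median 0.36, CDKN1A at 1.24 and ZMAT3 at 1.26). Immediate early genes rose in 5 of 15 (6, median 0.44, CCN1 at 0.80 and FOS at 0.79) and integrated stress genes in 5 of 20 with 1 lower (7 and 1, median 0.30, TRIB3 at 1.03 and HERPUD1 at 0.73). These 3 lists had an adjusted p = 0.407 with an estimated correlation.

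Falling lists in the success group were pluripotency, with 7 of 18 members lower (10 over the list alone, median -1.22), and the mitochondrially encoded genes, with 4 of 13 (10 over the list alone, median -0.72, MT-ATP8 at -1.13 and MT-CYB fell by 1.00). G2 and mitosis genes fell in 9 of 24 (11, median -0.26) and S phase genes in 4 of 20 (4, median -0.20, CDT1 at -0.59 and MCM4 at -0.57). With an estimated correlation the adjusted p was 0.407 for the first 3 lists and 0.528 for S phase. Ribosomal protein genes rose in 8 of 28 (18, median 0.41, RPL18 at 0.64 and RPL23 at 0.51; adjusted p = 0.468 with an estimated correlation). In G2 and mitosis the large values were CENPE at -2.37 (SE 0.54) and CENPF at -2.20 (SE 0.50), kinetochore proteins with long transcripts. These were also lower in both day 9 libraries that stood apart, CENPE by -2.29 and -2.96 and CENPF by -1.84 and -2.95 against the other 6. In these libraries the list medians against the other 6 were 0.52 and 0.74 for ribosomal proteins, 0.21 and 0.28 for p53 targets, 0.33 and 0.24 for integrated stress and 0.37 and 0.14 for hypoxia and glycolysis, where day 15 minus the other 6 was 0.56, 0.39, 0.34 and 0.66. The medians were 0.38 and 0.13 for BMP response, -0.09 and 0.05 for mesenchyme, 0.47 and -0.46 for pluripotency and 0.08 and 0.06 for G2 and mitosis, where day 15 minus the other 6 was 0.59, 0.74, -1.45 and -0.24. For eye field they were 0.40 and -0.46, for amnion -0.45 and 0.40, for surface ectoderm -0.06 and 0.54, and for retinoic acid 0.10 and 0.13. Immediate early genes had 0.14 and -0.31, S phase 0.18 and 0.29 and mitochondrially encoded genes 0.21 and -0.09.

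The count of 3677 genes in the success group was 7870 without both libraries that stood apart and 1917 with the length trend as a covariate, of which 1508 were the same genes. It was 1315 in a fit on only these 8 libraries and 8857 with sample weights in voom. Leaving out 1 library gave 2071, 1469, 1240 and 7196 without day 9 success replicates 1, 2, 3 and 4 and 1397 and 1272 without day 15 success replicates 1 and 2. Without both libraries 9 lists were called, and 6 calls were lost. In 4 of them the median in the voom fit stayed near its size or grew: eye field from 0.48 to 0.51 (adjusted p = 0.314), amnion from 0.56 to 0.78 (0.0807), mesenchyme from 0.76 to 0.71 (0.0645) and retinoic acid from 0.46 to 0.44 (0.0744). Immediate early genes went from 0.45 to 0.23 (0.135) and S phase from -0.20 to -0.12 (0.311). SIX6 kept its call in 11 of 22 alternatives and lost it without day 9 success replicate 1, 2 or 3 (adjusted p = 0.0871, 0.0643 and 0.135) or day 15 success replicate 1 or 2 (adjusted p = 0.139 and 0.132).

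**Figure D2:**
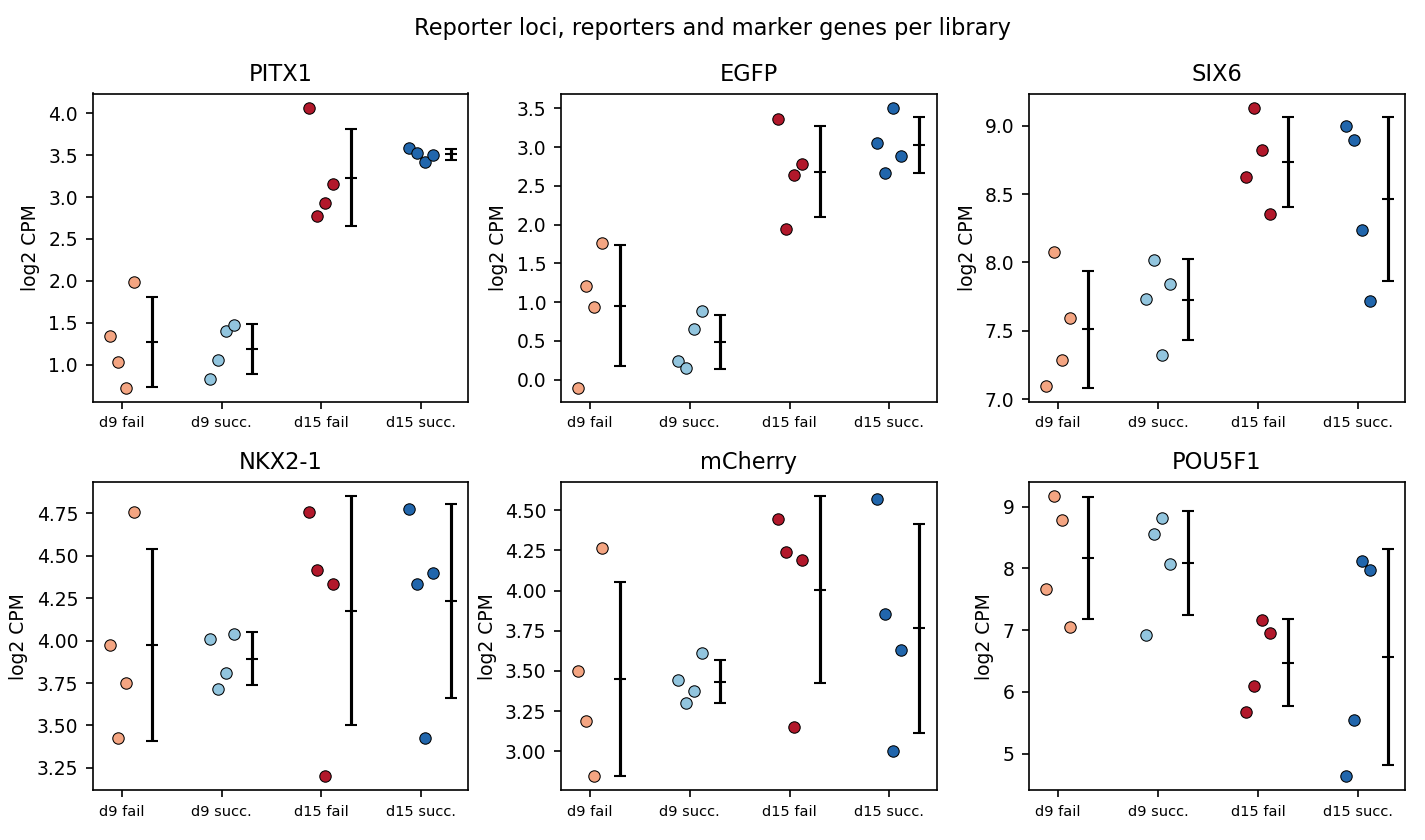
Level of 6 transcripts in log2 CPM in each library (points), with the mean and SD of each group of 4 libraries beside them. PITX1 and EGFP are higher in all day 15 libraries than in all day 9 libraries, and no transcript shown passed between fail and success at either day.

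The same time course in the fail group asks how organoids predicted to fail developed. PITX1 rose by 2.02 log2 (SE 0.30, adjusted p = 0.000957), from 2.45 ± 1.01 to 9.93 ± 4.57 CPM (SD, n = 4), EGFP by 1.72 (SE 0.36) and SIX6 by 1.20 (SE 0.27, adjusted p = 0.00890). NANOG, a pluripotency factor, fell by 2.75 (SE 0.79), from 8.27 ± 5.08 to 1.22 ± 0.787 CPM (SD, n = 4). The same comparison gave RAX 0.85 (SE 0.30, adjusted p = 0.0543), POU5F1 -1.81 (SE 0.67, adjusted p = 0.0625), LHX4 -1.13 (adjusted p = 0.0777), HESX1 -0.59, NKX2-1 0.22 and mCherry 0.54, none of which passed.

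In the fail group 1857 genes rose and 1785 fell, 548 and 609 of them at least 2-fold. Among genes chosen as in success, rises were DCT at 3.74 (SE 0.55), PDK4 at 3.57 (SE 0.41), SPARCL1, a matrix-associated glycoprotein, at 3.52 (SE 0.38) and S100A9 at 3.07 (SE 0.60). Besides NANOG the falls were the long non-coding RNAs LINC02700 at -3.35 (SE 0.93) and LINC00458 at -2.92 (SE 0.92), UNC13A at -2.76 (SE 0.65), SPIB at -2.72 (SE 0.73) and HPAT5 at -2.67 (SE 0.90). UNC13A was also lower in both day 9 libraries that stood apart, by -1.77 and -2.67, while NANOG was 1.08 higher in fail replicate 2. NANOG lost its call without day 9 fail replicate 3 or day 15 fail replicates 1, 2 or 4 and in limma voom. Its log2 fold change stayed between -3.21 and -2.37 in the 22 alternatives.

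Camera called 11 lists in the fail group, 7 up and 4 down, and none (0) with an estimated correlation. Hypoxia and glycolysis genes rose in 12 of 23 (19 over the list alone, median 0.62, P4HA2 at 0.90 and MXI1 at 0.70; adjusted p = 0.494 with an estimated correlation). BMP response genes rose in 8 of 17 (9, median 0.43, ID2 at 0.77 and ID4 at 1.02; adjusted p = 0.302) and retinoic acid genes in 5 of 15 with 1 lower (5 and 1, median 0.37, ALDH1A3 at 2.22 and CRABP1 at 0.79; adjusted p = 0.302). Eye field genes rose in 5 of 9 (7, median 0.69), p53 targets in 7 of 21 (12, median 0.34, CDKN1A at 1.15 and ZMAT3 at 1.10) and immediate early genes in 5 of 15 (5, median 0.44, CCN1 at 1.15 and DUSP1 at 0.86). Pluripotency genes fell in 11 of 18 (15, median -1.46, LIN28A at -1.37 and SALL4 at -0.66), S phase in 8 of 20 (9, median -0.30, MCM4 at -0.74 and CDT1 at -0.53) and G2 and mitosis in 11 of 24 (12, median -0.28, CENPE at -2.31 and BUB1B at -0.65). These 6 lists had an adjusted p = 0.613 with an estimated correlation. Ribosomal protein genes rose in 3 of 28 (0 over the list alone, median 0.33, RPS19 at 0.47 and RPLP2 at 0.43; adjusted p = 0.719) and mitochondrially encoded genes fell in 1 of 13 (0, median -0.53, MT-CYB at -0.80, and MT-ND1 at -0.67 without passing; adjusted p = 0.713). The ribosomal median was 0.52 and 0.74 in the day 9 libraries that stood apart, and its call was lost with the length trend (0.05, adjusted p = 0.118). In the same 2 libraries DUSP1 was higher by 0.65 and 0.69 than in the other 6, while CCN1 was at 0.29 and -0.26.

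The count of 3642 genes in the fail group was 7163 without both libraries that stood apart and 7770 with sample weights in voom. Leaving out 1 library gave 2204, 1350 and 2231 without day 9 fail replicates 1, 3 and 4 and 2337, 1450 and 1987 without day 15 fail replicates 1, 2 and 3. Without both libraries 10 lists were called, and the retinoic acid and mitochondrial calls were lost (adjusted p = 0.0684 and 0.146) with medians in the voom fit of 0.49 and -0.49, from 0.41 and -0.51. Both were also lost without day 9 fail replicate 2 alone (adjusted p = 0.0598 and 0.0681), the mitochondrial one also without day 9 fail replicate 4 (adjusted p = 0.0618).

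**Figure D3:**
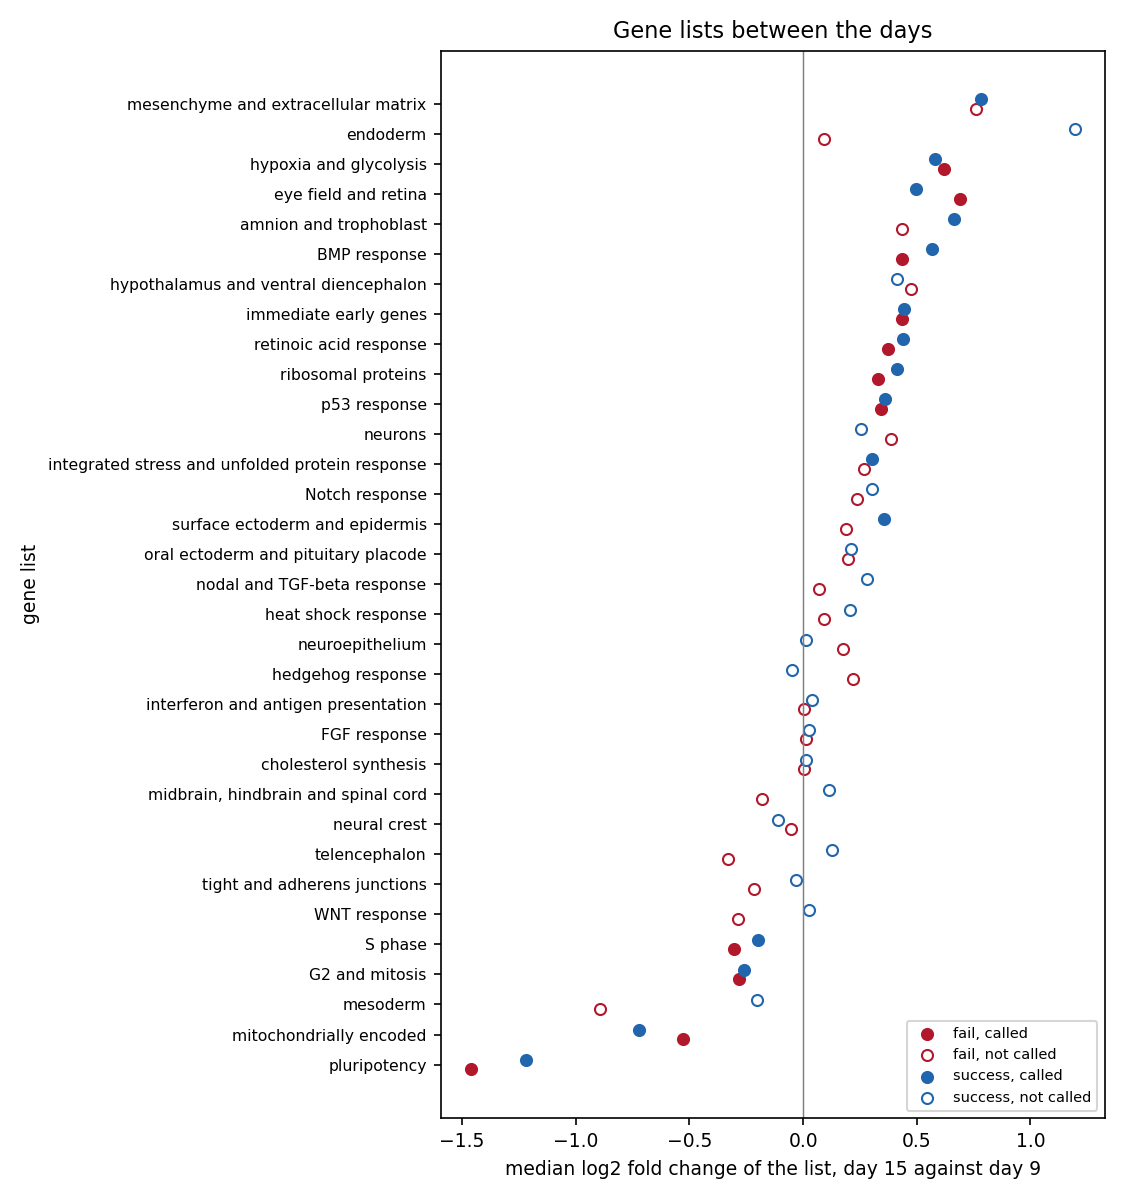
Median log2 fold change from day 9 to day 15 of each of the 33 gene lists, in fail (red) and success (blue). Filled points are lists called by camera with the preset correlation, and the pluripotency list has the lowest medians at -1.46 and -1.22.

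Lists that camera did not call between the days in either group included the tissues the organoids model. Fry called 16 lists in success, 14 of them called by camera too, and 8 in fail, all called by camera. The other 2 in success were oral ectoderm and pituitary placode (adjusted p = 0.0411) and heat shock (adjusted p = 0.00239). Of oral ectoderm and pituitary placode genes, 3 of 18 rose in success (median 0.21) and 3 of 18 in fail (median 0.20). Of hypothalamus genes, 3 of 17 rose and 1 fell in success (median 0.41), and 5 rose in fail (median 0.47). The neuron list had 3 higher and 1 lower of 16 in success and 6 and 1 in fail (medians 0.25 and 0.39), and the neuroepithelium list 3 and 4 of 16 in success and 6 and 4 in fail (medians 0.01 and 0.18). Medians in success and fail were 0.13 and -0.33 for telencephalon, 0.12 and -0.18 for midbrain, hindbrain and spinal cord, -0.11 and -0.05 for neural crest, -0.20 and -0.89 for mesoderm and 1.19 and 0.09 for endoderm. For signalling they were -0.05 and 0.22 for hedgehog, 0.02 and -0.29 for WNT, 0.03 and 0.01 for FGF, 0.30 and 0.24 for Notch and 0.28 and 0.07 for nodal and TGF-beta. They were 0.01 and 0.00 for cholesterol synthesis, 0.21 and 0.09 for heat shock, 0.04 and 0.00 for interferon and -0.03 and -0.22 for junctions. Called in success but not in fail were surface ectoderm (5 higher and 1 lower of 16 in fail, median 0.19), amnion (3 higher of 13, median 0.44), mesenchyme (7 higher of 19, median 0.76) and integrated stress genes (4 higher and 1 lower of 20, median 0.27). Of these, the mesenchyme difference between the groups was called in the interaction with the preset correlation, but not with an estimated one (adjusted p = 0.694) or in fry (adjusted p = 0.961). The median and the camera direction differed in sign for mesoderm, neuroepithelium, FGF, cholesterol and midbrain genes in success and for FGF and cholesterol genes in fail, none of them called by camera or fry. Pituitary hormone genes were too few for a list test.

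Day changes of both outcome groups, which share no libraries, went together. Of the genes called, 1260 rose in both groups, where 191 are expected from independent lists of these sizes. In both 1215 fell, where 198 are expected, and 0 went opposite ways. Both comparisons use the same estimate of spread per gene, which can raise the overlap above these expectations, and both share the library series. Across the 17164 genes, which are not independent replicates, log2 fold changes of both groups correlated at 0.874 (Pearson) and 0.866 (Spearman).

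Success against fail at day 9 asks whether organoids predicted to succeed already differed early. No gene passed: PITX1 was at -0.16 (SE 0.31, 95% interval -0.81 to 0.50), SIX6 at 0.19 (SE 0.27), POU5F1 at -0.15 (SE 0.64) and NKX2-1 at -0.17 (SE 0.32), with 4 libraries per group. RAX lay at -0.09, HESX1 at 0.13, LHX4 at 0.08, mCherry at -0.11 and EGFP at -0.63 (SE 0.38), none of which passed. Smallest p-values belonged to ASB12 at 1.61 (SE 0.40), PHACTR3 at 0.84, the neuropeptide gene GRP at -1.19, TMEM176B at 1.04, KLHL32 at 0.96 and ATP4A at 1.14 (SE 0.37), none past the adjustment (adjusted p = 1.00). Their levels were low, with group means from 0.179 CPM for ASB12 in fail to 1.88 for PHACTR3 in success. EdgeR, DESeq2 and limma voom each called 0 genes, with 73 genes at an unadjusted p under 0.05 in edgeR, 74 in DESeq2 and 87 in voom against 858 expected by chance. That number depended on the libraries and the fit: 120, 233 and 134 without fail replicates 1, 2 and 4, 152, 136 and 185 without success replicates 1, 3 and 4. It was 240 without both libraries that stood apart, 159 with the replicate number as a block, 151 with the length trend, 529 with the trend and the block, 501 with sample weights, 330 with no filter and 38 in a fit on only these 8 libraries, each with 0 calls. The 95% interval lay within a 2-fold change either way for 83.2% of the genes, and for 97.8% of the 12010 genes with at least 5 CPM.

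Camera called 11 lists at day 9, of which 10 were lower in success, although no member (0) of any list passed alone, also adjusted over the list alone. The lowest medians were midbrain, hindbrain and spinal cord (-0.59 over 13 genes, the caudal factor CDX2 at -1.73, SE 0.94, and EGR2 at -0.66), endoderm (-0.56 over 12, SOX17 at -1.33 and GATA4 at -0.89) and mesoderm (-0.35 over 16, TBXT, a factor of the primitive streak, at -1.51, SE 0.92). Also lower were nodal and TGF-beta (-0.17, LEFTY1 at -1.38 and TGFB2 at 0.40), WNT (-0.15, LEF1 at -0.49 and NKD1 at -0.29), amnion (-0.14, GATA3 at -0.31) and mesenchyme (-0.12, FN1 at -0.29 and PDGFRA at -0.35), and further neural crest (-0.10, ETS1 at -0.55 and TFAP2B at -0.56), Notch (-0.10, DLL4 at -0.75 and DLL3 at -0.47) and hedgehog (-0.07, SHH at -1.43 and NKX6-1 at -0.53). Ribosomal proteins were higher (0.09, RPLP0 at 0.16 and RPS18 at 0.15). Among the members named, SHH had the lowest level, at 0.178 CPM in fail and 0.0588 in success. With an estimated correlation the adjusted p was 0.195 for midbrain and WNT, 0.407 for neural crest, 0.417 for mesoderm, 0.426 for endoderm, 0.488 for Notch and nodal, 0.521 for amnion, mesenchyme and hedgehog and 0.937 for ribosomal proteins, and the smallest from fry was 0.980. TBXT was 3.31 and 2.29 higher and CDX2 3.22 and 1.72 higher in the fail and the success library that stood apart than in the other 6. Without both libraries 11 lists were called, but only 6 of them were among those above: neural crest, hedgehog, Notch, nodal and TGF-beta and ribosomal proteins lost their calls (adjusted p = 0.175 to 0.924). The neural crest median in the voom fit did not shrink, from -0.09 to -0.12. The medians of the others went from -0.09 to 0.04 (hedgehog), -0.12 to -0.0025 (Notch), -0.18 to -0.03 (nodal and TGF-beta) and 0.08 to -0.0068 (ribosomal proteins). The list count was 7 without day 9 fail replicate 1 and 7 without day 9 success replicate 4. The ribosomal list was called in the opposite direction, lower in success, with the length trend (median in the voom fit from 0.08 to -0.02, adjusted p = 0.0289), with the trend and the block (-0.02, adjusted p = 0.0229) and without day 9 success replicate 4 (-0.13, adjusted p = 3.92e-07). Without that replicate the hedgehog and Notch medians were 0.05 and 0.02 and their calls were lost (adjusted p = 0.820 and 0.802). The endoderm call was lost without day 9 fail replicate 1 (0.02, adjusted p = 0.0859).

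Success against fail at day 15 asks the same at the later day, and again no gene passed. PITX1 was at 0.18 (SE 0.28, 95% interval -0.40 to 0.77), RAX at -0.52 (SE 0.30), LHX4 at 0.77 (SE 0.45), POU5F1 at 0.64 (SE 0.65), HESX1 at 0.32, SIX6 at -0.21, NKX2-1 at 0.03, EGFP at 0.30 and mCherry at -0.21, with 4 libraries per group. The smallest p-values were those of MASP1, a protease of the complement lectin pathway, at 0.66 (SE 0.15), with 7.99 ± 1.65 CPM in fail and 12.6 ± 1.24 in success (SD, n = 4), OTOA at -1.23 (SE 0.29), CEBPA-DT at 0.60, the unnamed gene ENSG00000272512 at -2.87, the rostral hindbrain gene HOXB1 at -2.50 (SE 0.77) and C6orf163 at 1.40 (adjusted p = 1.00 for each). Levels were low for ENSG00000272512, at 0.426 CPM in fail and 0.0503 in success, and for HOXB1, at 1.04 ± 1.04 and 0.178 ± 0.163 (SD, n = 4). EdgeR, DESeq2, limma voom and edgeR with the replicate number as a block called 0 genes, and 224 genes had an unadjusted p under 0.05 in edgeR, 239 in DESeq2 and 243 in voom, where chance gives 858. With 0 calls each, the number was 1022 without both day 9 libraries that stood apart, 450 with the block, 362 with the length trend, 1198 with the trend and the block, 552 with no filter, 902 with sample weights and 690 in a fit on only these 8 libraries. It was 139 and 377 without fail replicates 2 and 4 and 420 without success replicate 1. For 80.4% of the genes the 95% interval stayed within 2-fold either way.

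Of the lists, 13 were called at day 15, 6 higher and 7 lower in success, again with no member (0) passing alone. Lower in success were eye field (-0.27 over 9 genes, RAX at -0.52 and LHX2 at -0.44), neurons (-0.25 over 16, NHLH1 at -0.77, SE 0.31, and doublecortin, DCX, at -0.43, SE 0.20) and mitochondrially encoded genes (-0.24, MT-ND1 at -0.31 and MT-ND3 at 0.25). So were hedgehog (-0.24, PTCH1 at -0.39), hypothalamus (-0.21, FGF10 at 0.42), Notch (-0.21, DTX4 at -0.42 and LFNG at -0.19) and neuroepithelium (-0.19, CDH2 at -0.22 and ZEB2 at -0.19). Higher were mesoderm (0.45 over 16, MEOX1 at 0.71 and GATA4 at 0.78), ribosomal proteins (0.19, RPL11 at 0.25 and RPL4 at 0.20) and surface ectoderm (0.19, ESRP1 at 0.32 and CLDN7 at 0.26). So were oral ectoderm and pituitary placode (0.17, LHX4 at 0.77 and SIX4 at 0.18), junctions (0.16, MARVELD2 at 0.45) and S phase (0.10, CDC45 at 0.19 and TYMS at 0.16). With an estimated correlation the adjusted p was 0.457 for neurons, neuroepithelium and hedgehog, 0.613 for S phase and 0.527 for the other 9, and the smallest from fry was 0.772. At day 15 each success library had a lower length slope than the fail library of its number. Mean slopes were -0.0902 ± 0.0380 in success and -0.0438 ± 0.0591 in fail (SD, n = 4). The 28 ribosomal protein genes took 6.09 ± 0.284% and 5.48 ± 0.425% of the counts. With the length trend as a covariate 11 lists were called, 10 of them among these 13. The list count was 14 without both day 9 libraries that stood apart, 5 without day 15 fail replicate 2 and 8 without day 15 success replicate 4. Without the latter the calls of the mitochondrially encoded and S phase lists ended and their medians in the voom fit turned, from -0.34 to 0.04 (adjusted p = 0.736) and from 0.08 to -0.0011 (adjusted p = 0.934).

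The interaction of outcome and day asks whether the difference between success and fail changed from day 9 to day 15. PITX1 differed by 0.34 (SE 0.41), EGFP by 0.93 (SE 0.50), POU5F1 by 0.79 (SE 0.92), LHX4 by 0.69, RAX by -0.44, SIX6 by -0.40, NKX2-1 by 0.20, HESX1 by 0.19 and mCherry by -0.10, with 4 libraries per group, and none passed. GRP at 1.83 (SE 0.45), LINC01530 at -2.04, ENSG00000289594 at -1.42, MASP1 at 0.74 (SE 0.22), ENSG00000272512 at -3.55 and LINC01270 at 1.45 had the smallest p-values (adjusted p = 1.00). All of these but MASP1 had low levels, with group means up to 1.97 CPM for LINC01270 in day 9 fail. EdgeR and DESeq2 called 0 genes, limma voom 0, and 132, 123 and 138 genes had an unadjusted p under 0.05. In edgeR this became 739 and 239 without day 9 success replicate 4 and fail replicate 4, 222 without day 15 success replicate 1, 627 without both libraries that stood apart, 267 with the block, 267 with the length trend, 964 with both, 512 with no filter, 208 with the library number as a block and 85 with at least 1 CPM in 4 libraries, and it was 962 in voom with sample weights, all with 0 calls. Lists called were mesoderm (median 0.88, GATA4 at 1.67 and MEOX1 at 1.20), endoderm (1.39, FOXA1 at 1.63), midbrain, hindbrain and spinal cord (0.58, CDX2 at 2.85 and HOXB1 at -1.62), WNT (0.33, APCDD1 at 0.74 and LEF1 at 0.65) and mesenchyme (0.20, FN1 at 0.42 and PDGFRA at 0.54). The others were junctions (0.11, PKP3 at 0.38 and MARVELD2 at 0.41), S phase (0.10, E2F8 at 0.62 and CDC45 at 0.18), ribosomal proteins (0.08, RPL11 at 0.18 and RPL23 at 0.16) and mitochondrially encoded genes (-0.20, MT-ATP8 at -0.61 and MT-ND1 at -0.27). With an estimated correlation none (0) was called: the adjusted p was 0.286 for WNT, 0.517 for mesoderm, endoderm and midbrain, 0.742 for ribosomal proteins and 0.694 for the other 4. The 9 lists became 18 with the replicate number as a block. Without both libraries that stood apart 13 were called, 7 of them among the 9, and the calls of midbrain and of mesenchyme were lost (adjusted p = 0.158 and 0.0744) with medians in the voom fit of 0.35 and 0.28, from 0.37 and 0.20. They were 2 and 5 without day 9 success replicates 2 and 4, 4 and 5 without day 15 fail replicates 2 and 4, and 16 and 5 without day 15 success replicates 1 and 4. In the voom fit that camera used, 6 of the 9 medians turned and lost the call when 1 library was left out. Endoderm went from 0.65 to -0.05 without day 15 success replicate 2 (adjusted p = 0.117), mesenchyme from 0.20 to -0.02 without replicate 3 (adjusted p = 0.451). Ribosomal proteins went from 0.12 to -0.03 without day 9 fail replicate 2 (adjusted p = 0.704). Without day 15 success replicate 4, mitochondrially encoded genes went from -0.30 to 0.03 (adjusted p = 0.902), S phase from 0.09 to -0.0044 (adjusted p = 0.871) and junctions from 0.12 to -0.02 (adjusted p = 0.746).

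Spread was taken as the distance of each library to the mean of the other libraries of its group. At day 15 it was 28.4 ± 1.5 in success, against 20.3 ± 0.990 in fail (SD, n = 4, exact permutation p = 0.0286). This is the smallest p these sizes allow, and it did not pass adjusted over both days (0.0571). Distances within a group share libraries, and the permutation ignored the pairing by number, so this p cannot decide whether success libraries varied more. In the success group, replicates 1 and 2 were at 33.3 and 33.7 on the first principal component and replicates 3 and 4 at 9.96 and 14.5. At day 9 the distances were 30 ± 12.5 in success and 27.5 ± 7.27 in fail (SD, n = 4, exact permutation p = 0.771). Differences between success and fail at day 9 and at day 15 correlated at 0.103 (Spearman) and -0.01 (Pearson) across 17164 genes, which are not replicates. The Spearman value was -0.128 without both day 9 libraries that stood apart.

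Reporter transcripts followed their loci across the 8 libraries of a day to different degrees. NKX2-1 and mCherry correlated at r = 0.886 at day 9 (exact permutation p = 0.0125, adjusted 0.0250 over 4 relations, Spearman 0.905, p = 0.00456) and 0.920 at day 15 (exact permutation p = 0.00184, adjusted 0.00734, Spearman 0.881, p = 0.00724). PITX1 and EGFP correlated at r = 0.467 at day 9 (exact permutation p = 0.244, Spearman 0.167, p = 0.703) and 0.765 at day 15 (exact permutation p = 0.0271, adjusted 0.0361, Spearman 0.667, p = 0.0831). These permutations treated the 8 libraries of a day as independent. At day 15 same-number libraries were taken as pairs, so the p-values of that day may be too small. Without the 2 libraries farthest from the median of the locus, r was 0.740, 0.753, 0.136 and 0.404 in the same order. Leaving out extremes narrows the range of levels, which can lower r but need not. At day 9 PITX1 had 30 to 80 counts per library and EGFP 16 to 68, against 202 to 559 for NKX2-1. Counting error weighs more at such low counts, so the lower r of PITX1 and EGFP at day 9 does not rank the reporters. Further pituitary genes lay below the count filter: LHX3 had 1 to 17 counts per library, and POU1F1, TSHB and FSHB had 0 in all 16 libraries, which allows up to 3 counts each, or 0.184 CPM in the smallest library. GH1, GH2, PRL and LHB reached at most 8, 5, 3 and 2 counts. These limits cover counting error only.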

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

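Tests chosen only after the result was seen were the comparison of risen and fallen genes in the libraries that stood apart, the length trend as a covariate, the tests of a property shared with day 15, the counts without both libraries, the use of the counts with a planned block to weigh the missing calls, and the list counts over other splits.

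Day 9 success replicate 4 lay far from the other libraries of its group in 2 library measures, a length slope of -0.192 and a ribosomal protein share of 6.48%, and day 9 fail replicate 2 in 1, a length slope of -0.0966. These were 3 of 20 library measures tested for a distant library. Among the genes named, 23 of 338 sets of a gene and a group (6.80%) had a distant library, where chance gives about 5%, and 12 of the 23 were in day 9 success replicate 4. In log2 CPM, its ribosomal genes were high, with RPLP0 at 12.26, RPS18 at 11.49, RPL11 at 10.95 and RPL23 at 10.70, and so were BAMBI at 5.55 and MYL7 at 0.93. Its low values were CENPF at 5.75, NKD1 at 3.27, CENPE at 2.51, ATP4A at -1.27, ENSG00000272512 at -1.78 and EGR2 at -2.13. CENPE was also far from its group in day 9 fail replicate 2, at 3.18. The others were TMEM176B at 0.95 and MT-CYB at 8.82 in day 9 success replicate 2 and SHH at -2.68 in day 9 fail replicate 1. At day 15 they were LHX2 at 6.62, MT-ND1 at 6.74, SEC31B at -0.26 and PKP3 at 4.65 in success replicate 4, CCN1 at 5.35 in success replicate 1, TYMS at 7.36 in fail replicate 4 and LINC02700 at -2.23 in fail replicate 1.

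Both day 9 libraries that stood apart had less of long transcripts. Length as the whole cause is argued against, since after a spline on length they still lay 1.83 and 2.59 times as far out as the farthest of the other 6. The 500 genes of this distance were the most variable with both libraries included, which favours large ratios. Over all 14704 genes the distances after the spline were 55.6 and 80.1, against at most 36.4 in the other 6. Among genes with a change of at least 2-fold, called without both libraries, those that rose shifted by 31.6 and 17.7% as much as those that fell, but over all 2888 risen and 2944 fallen genes so called the shifts were 60.3 and 83.3% against 72.2 and 113% of the day change. Genes whose day change ran against the length trend had a median shift of 65.0 and 105% of that change, so a later stage and another property shared with day 15 cannot be told apart, since both give such a shift. For nuclear-retained RNA, 7 such RNAs had medians of -0.42 and -0.41 against -0.22 in the lowest of the other 6. The members were split (MIAT, TUG1 and SNHG14 lay below all of the other 6 in both, PVT1 only in success replicate 4, and DLEU2 was higher, by 0.34 and 0.43). Other nuclear RNAs had been seen to be low before that list was written. These values were not corrected for length, so a lower yield of nuclear RNA cannot be told apart from the loss of long transcripts.

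Between the days, 3677 genes were called in success and 3642 in fail, and day and library series cannot be told apart in this design. A length trend as the whole cause is argued against, since 41.0% of the calls in success and 62.6% of those in fail were left with the trend as a covariate. Genes that rose in both groups had shifted in the libraries that stood apart by 31.4 and 37.0% of the day change and genes that fell by 52.0 and 76.0%, but these calls favour genes that those libraries did not shift. Over genes called without both libraries the shifts were 60.3 and 83.3% for rises and 72.2 and 113% for falls. A property shared by day 15 and those libraries may therefore account for part of the typical change, or for all of it. Development between the days stays open as the biological explanation and was not tested apart from the library series.

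No gene (0) passed between success and fail at either day in edgeR, DESeq2 or limma voom, with 73 and 224 genes at an unadjusted p under 0.05 in edgeR, 74 and 239 in DESeq2 and 87 and 243 in voom. Low power stays open: 67.7 and 72.3% of simulated 2-fold changes were called, but 4.95 and 4.74% of simulated unchanged genes had an unadjusted p under 0.05 against 0.425 and 1.31% of the real genes, so the simulation does not give the real power. The 95% interval lay within a 2-fold change for 83.2% of the genes at day 9 and 80.4% at day 15, which argues against larger differences in those. Leaving out both day 9 libraries that stood apart and the replicate number as a block gave 0 calls each, but the counts at an unadjusted p under 0.05 went to 240 and 1022 and to 159 and 450, so a spread from these libraries or numbers that hides a difference stays open. Little difference in RNA between the predicted outcomes at these days stays open too.

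The interaction test called 9 lists that differed between the outcome groups in their day change. Their medians were 0.58 for midbrain, hindbrain and spinal cord, 0.88 for mesoderm, 1.39 for endoderm, 0.20 for mesenchyme, 0.33 for WNT, 0.10 for S phase, 0.085 for ribosomal proteins, -0.20 for mitochondrially encoded genes and 0.11 for junctions. In 6 of the 9 the median turned and the call was lost when 1 library was left out, as given with the interaction. None (0) was called with an estimated correlation (smallest adjusted p = 0.286) or in fry (0.961). Chance is not excluded for these lists, as 54 of 100 splits gave as many, with 22 in the highest other split.

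Other splits of the libraries were run for each comparison. For success against fail and the interaction the real split called 0 genes, and as no split can give fewer, the 35 of 35 at each day (highest other 21 at day 9 and 1 at day 15) and 100 of 100 (highest other 245) decide nothing. For the lists chance is not excluded, with 8 of 35 at day 9 (real 11, highest other 18) and 15 of 35 at day 15 (real 13, highest other 22). For day 15 against day 9 in fail, chance is argued against for the genes, as 1 of 35 splits, the real one, reached 3642 and the highest other gave 0. This is the smallest share that 35 splits allow, and it was not adjusted over the comparisons. The other splits also mix the days, which adds a day difference to the spread within their groups. In success chance is not excluded by this count, as 2 of 35 splits reached the real 3677 and the highest other gave 4975. Called genes came in 3 other splits (4975, 2764 and 2682), all of which kept day 9 success replicates 1 to 3 together and put replicate 4, which stood apart, with day 15 libraries. Between the outcome groups, which share no libraries, 1260 called genes rose and 1215 fell in both, where 191 and 198 are expected, and 0 went opposite ways. Both groups share the estimate of spread per gene and the library series, so these expectations are too low as a measure of chance. For lists of the day comparisons, 6 of 35 splits in success (real 15, highest other 22) and 16 of 35 in fail (real 11, highest other 16) gave as many. At day 15, where numbers were taken to pair the libraries, the 7 other splits that part all pairs gave at most 0 genes and 19 lists, against 0 and 13 in the real one.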

How the results depend on the processing

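Leaving out both day 9 libraries that stood apart and the length trend, alone or with the replicate block, were chosen after seeing the data. No called gene named in a day comparison reversed: 20 of 42 in success and 14 of 32 in fail kept the call in every alternative. Where values moved, the cause was not tested, except that a minimum change of 1 log2 calls fewer genes by its construction and fewer libraries give less power.

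Counts of genes were 0 for success against fail at day 9, at day 15 and for the interaction in every alternative with a count. In success the 3677 genes between the days became 8857 in voom with sample weights, 1315 with only the 2 groups compared, 1310 with at least 1 log2, 7870 without both libraries that stood apart and 1917 with the length trend. In fail the 3642 became 7770 with sample weights, 1157 with at least 1 log2 and 7163 without both libraries. With the replicate number as a block they were 4349 and 4309, and with the library number, which differs from it between the days, 3995 and 3713. For success against fail and the interaction the counts at an unadjusted p under 0.05 did move: 330, 552 and 512 with no filter, 151, 362 and 267 with the length trend and 529, 1198 and 964 with the block added, from 73, 224 and 132.

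Camera with the correlation estimated called 0 lists at day 9, 0 at day 15, 1 between the days in success, 0 in fail and 0 for the interaction. Fry called 0 at day 9, 0 at day 15, 16 in success (14 of them the same), 8 in fail (all the same) and 0 for the interaction. Without both libraries that stood apart 9 lists were called in success, 11 at day 9 (6 the same) and 13 for the interaction (7 the same). The interaction had 18 lists with the replicate block and 19 with the length trend and the block. Agreement of the outcome differences between the days was -0.128 without both libraries.

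In log2, values that changed sign at day 9 in voom with sample weights were LHX4 at -0.36, RAX at 0.14, HESX1 at -0.043, POU5F1 at 0.40, LEFTY1 at 0.42, RPLP0 at -0.023 and RPS18 at -0.035. Without both libraries they were LHX4 at -0.35, RAX at 0.25, POU5F1 at 0.29, RPLP0 at -0.0036, RPS18 at -0.0153 and the medians of the hedgehog list at 0.038 and the ribosomal list at -0.0068. With the length trend they were RPLP0 at -0.0055, RPS18 at -0.0153 and the ribosomal list at -0.018, and with the block added RPLP0 at -0.0063, RPS18 at -0.016, the ribosomal list at -0.0202 and mCherry at 0.022. Others were POU5F1 at day 15 (-0.24, sample weights), NKX2-1 at day 15 (-0.0047, library totals alone) and NKX2-1 in fail (-0.057, sample weights). In the interaction POU5F1 was at -0.64 and mCherry at 0.061 with sample weights, and mCherry at 0.065 without both libraries. No gene among these was called in its comparison, while camera had called the ribosomal and hedgehog lists at day 9.

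Leaving out each library in turn gave 0 to 0 genes at day 9, at day 15 and for the interaction, 1240 to 7196 in success and 1350 to 5161 in fail. Lists were 7 to 14 at day 9, 5 to 18 at day 15, 10 to 15 in success, 10 to 14 in fail and 2 to 16 for the interaction. The spread in fail minus success was -9.75 to 7.90 at day 9 and -10.4 to -6.26 at day 15, and the agreement -0.334 to 0.263. At day 9 sign changes lay in PITX1 (-0.32 to 0.16), LHX4 (-0.19 to 0.36), RAX (-0.27 to 0.11), NKX2-1 (-0.34 to 0.17), POU5F1 (-0.41 to 0.23), mCherry (-0.29 to 0.24), DLL3 (-0.83 to 0.0059), RPLP0 (-0.17 to 0.32), RPS18 (-0.19 to 0.32), the hedgehog list (-0.25 to 0.049) and the ribosomal list (-0.13 to 0.20). At day 15 they lay in NKX2-1 (-0.20 to 0.24), the S phase list (-0.0011 to 0.16) and the mitochondrial list (-0.50 to 0.039). In the interaction they lay in NKX2-1 (-0.14 to 0.41), HESX1 (-0.11 to 0.47), mCherry (-0.46 to 0.11), the ribosomal list (-0.026 to 0.31) and the mitochondrial list (-0.45 to 0.028). Medians of further lists crossed 0 while camera kept its direction and the call was lost: at day 9 endoderm (0.015 without fail replicate 1) and Notch (0.016 without success replicate 4), and in the interaction endoderm (-0.053), mesenchyme (-0.016), S phase (-0.0044) and junctions (-0.024), without day 15 success replicates 2, 3, 4 and 4.

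Calls of named genes and lists were lost 58 times with an estimated correlation, 37 in fry, 26 with at least 1 log2, 16 without both libraries, 16 with the length trend, 8 in voom and 7 with only the 2 groups compared. Between 7 and 25 were lost without a single library, most without day 15 fail replicate 2. At day 9, libraries of the same replicate number correlated from -0.217 to 0.686 and 2 of 4 matched best with their own number, so the block rests on day 15. Depth limits genes near the filter, such as LHX3 with 1 to 17 counts.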

Other observations

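All tests in this part were chosen after values were seen, except the count of pairings of libraries.

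Several genes of tissue identity changed between the days in lists that camera did not call in both groups, and they were chosen here after their values were seen. FOXE1, a transcription factor of the oral ectoderm and thyroid, rose by 2.75 (SE 0.31) in success and 2.57 (SE 0.31) in fail. TBX2, which acts in the ventral hypothalamus and the eye, rose by 2.59 and 2.99 (SE 0.65 and 0.64), and the neural factors SOX1 and HES5 by 1.65 and 1.67 in success and 2.43 and 1.68 in fail. TUBB3, a neuronal tubulin, rose by 1.13 and 1.36, and TP63, a factor of stratified epithelium, by 2.12 and 1.95. The mesoderm factor TBX6 fell by 1.33 and 1.44. POMC, the precursor of corticotropin, rose by 2.62 (SE 0.38, adjusted p = 0.000916) in success and 1.87 (SE 0.37, adjusted p = 0.00516) in fail. The hormone subunit gene CGA was at 0.78 and -0.83 (SE 0.97 each) and did not pass.

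Day 15 libraries differed in how much of the pluripotency list they held. Its mean was 4.31, 4.6, 5.17 and 5.10 log2 CPM in fail replicates 1 to 4 and 3.58, 4.02, 5.76 and 5.64 in success replicates 1 to 4. POU5F1 was at 4.64 and 5.55 log2 CPM in success replicates 1 and 2 and at 8.13 and 7.97 in replicates 3 and 4. Over the 8 libraries, as deviations from the group mean, the list correlated with neuroepithelium at r = -0.802 (exact permutation p = 0.0203, adjusted 0.0581 over 8 relations, Spearman -0.810), with hypothalamus at -0.776 (exact permutation p = 0.0203, adjusted 0.0581, Spearman -0.762) and with mesoderm at 0.806 (exact permutation p = 0.0218, adjusted 0.0581, Spearman 0.810). Without the 2 farthest libraries r was -0.781, -0.858 and 0.718. Neurons were at -0.736 (adjusted 0.0628), eye field at -0.681, surface ectoderm at 0.361, oral ectoderm at 0.264 and endoderm at 0.0567. No relation passed the adjustment, and a replicate number holds too few libraries (2) for a value within it. The permutations treated the 8 libraries as independent, although same-number libraries were taken as pairs, so these p-values may be too small.

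A library number may mark a shared culture batch. At day 15, 3 of 24 pairings of fail and success libraries gave at least the 15 genes called for the real numbers, with 70 in the highest other pairing, so a batch and other differences between libraries cannot be told apart with 4 pairs. At day 9 the real pairing called 0 genes, so that 24 of 24 pairings reach it by construction and the count decides nothing. The 6 pairings with a call, up to 2939 genes, all put the 2 libraries that stood apart together. Across the days, libraries of the same number had a median correlation of 0.313 in their deviations from the group mean (12 pairs), against -0.0990 for other numbers (52 pairs).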
